A study of Mus musculus with 15 samples.

How the data were processed

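RNA sequencing of mouse skin was analysed in 15 libraries from K14CreERTM/LSL-SOX2 mice, a line in which a Cre recombinase driven by the keratin 14 promoter and activated by tamoxifen is meant to switch on a silent SOX2 transgene. Per the labels' protocols, tamoxifen at 5 mg/ml in 200 µl of ethanol, or the same volume of ethanol as vehicle, was applied to the skin. RNA was prepared with Trizol and a QIAGEN column kit, libraries were made with NEBnext and NuGen kits, and sequencing was on the HiSeq3000. Which library was made with which kit is not given in the sources used here, so no batch by kit could be formed. Mice are of a mixed 129/SvEv/C57/B16 X CD-1 strain per the labels.

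The authors mapped reads to the mouse genome build mm10 with TopHat and computed RPKM (reads per kilobase of gene, scaled to the mapped reads of the library) per gene with Partek, per the file headers. TopHat2 2.1.0, bcl2fastq and Partek are named in the submitters' processing notes. The gene annotation, the counting rule and the use of strand are not given in the sources used here. The deposited RPKM table holds 24543 genes, of which 3059 are at 0 in every library. The authors' second table gives group means of log2 RPKM and, from an ANOVA, a p-value and q-value per contrast, per the file headers. Each deposited ratio and signed fold change in it is the linear ratio of those log2 group means. The offset added before the log is not stated, and an offset of 0.1 gave back all 24543 deposited group means within 0.0001. No p-value is given there for 3197 genes. A deposited sheet of SOX2 targets lists 81 genes, with 1215 of 1215 values equal to the RPKM table, and how its genes were chosen is not given in the sources used here. A deposited sheet of samples gives the count of alignments and the count of reads assigned to a gfp sequence for each library.

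Treatment names conflict for the 8 wounded libraries. The sample records, the target sheet and a column for the old group in the sample sheet give one treatment name, and the RPKM table, the ANOVA table and a column for the new group in the sample sheet give the other. For the 7 unwounded libraries all sources give the same name. The headings of these columns mark the gene tables' names as the later ones of the submitters. The reason for the change is not given in the sources used here. Groups were taken from the sample records. In the text, wounded set A denotes the 4 libraries recorded as tamoxifen wounded, which the gene tables name vehicle wounded, and wounded set B denotes the 4 recorded as vehicle wounded, which the gene tables name tamoxifen wounded. The replicate numbers are those of the sample records.

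Library depth was 39277860 to 75102345 alignments. In the shallowest library an RPKM of 1 for a gene of 1 kb corresponds to 39.3 reads, and 3 reads, taken as the floor, correspond to 0.0399 to 0.0764 RPKM per library for such a gene. These floors cover counting error only. RPKM values are not counts, so no count model was fitted.

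The groups, comparisons, tests, gene lists, rule for named genes and alternatives were chosen before the data were examined, except those named here or in later parts as added after seeing the data. Differences were tested with limma 3.58.1 in R 4.3.3 (trend in the prior variance, two-sided) on log2(RPKM + 0.5), over 13922 genes with an RPKM of at least 1 in at least 3 libraries. All 15 libraries entered one model of 4 groups with 11 residual degrees of freedom and 2.57 prior degrees of freedom. Every adjusted p in the text is limma's, by Benjamini-Hochberg over the genes tested within a comparison, with a threshold of 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, and errors beside them are limma's standard errors. Errors beside RPKM means are SDs.

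By the sample records 5 comparisons were made: tamoxifen against vehicle in unwounded skin, the same in wounded skin, wounded against unwounded within each treatment, and the interaction of treatment and wounding. After the conflict of names was seen, 3 comparisons were added in which the wounded sets carry the gene tables' names. The study's design text describes groups of 3 or 4 without saying whether each library is a separate mouse. If some are not, the p-values measure only the spread between these samples, which may be technical.

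The replicate numbers were checked for pairing by the correlation across genes of the libraries' deviations from their group means. All 4 same-numbered pairs of sets A and B were over 0.1 (0.123 to 0.43), and in each of the other 5 pairs of groups at least 1 was not. The numbers were therefore taken to pair sets A and B alone. This rests on the values, since what a number marks is not given in the sources used here.

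Sox2 was also compared with a two-sided exact permutation test of the mean log2(RPKM + 0.5), run with scipy 1.17.1 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Correlations of fold changes were computed across genes, which are not independent replicates, and only between comparisons that share no library. Figures were drawn with matplotlib 3.10.9.

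Sets of genes were tested with camera in limma at a preset correlation of 0.01 between genes, with adjustment over the 29 lists of a comparison, each with at least 4 tested members. The fixed lists cover EGFR ligands and receptors, MEK/ERK response genes, wound-activated keratinocyte genes, cell cycle genes, inflammatory cytokines and chemokines, epithelial antimicrobial and alarmin genes, growth factors of the wound, wound matrix genes, oral epithelium-associated genes, other Sox genes, oestrogen receptor targets and the deposited SOX2 target sheet. Marker lists cover basal and differentiated keratinocytes, hair follicle and hair shaft, Merkel cells, melanocytes, sebaceous gland, neutrophils, macrophages and monocytes, T cells, dendritic and Langerhans cells, mast cells, fibroblasts, endothelial cells, adipocytes, skeletal muscle, Schwann cells and red blood cells. Of the 71 tested genes of the SOX2 target sheet, 16 are also in another list. After seeing the data, 2 further lists were added, of interferon-stimulated genes and of targets of the transcription factor NRF2. With a correlation estimated per list, 0 lists passed in any of the 8 comparisons, while the directional test of fry called 25 lists for tamoxifen against vehicle in unwounded skin.

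The text names Sox2, the EGFR ligands and receptors, and the 5 largest rises and 5 largest falls of each comparison. For these, adjusted p was under 0.05, the libraries of both groups did not overlap and the higher group mean RPKM was at least 2. For the interaction the condition on overlap was dropped. It also names the 3 members with the smallest p of each list called in its direction, from which the text takes examples, and those of the MEK/ERK, wound-activated keratinocyte and cell cycle lists in any case. Of the genes that this rule takes, at least 1 is not reported here. Genes of predicted models and Y-linked genes were replaced by the next gene. Of 56 symbols looked up, 55 were found once in GENCODE M21, an annotation of GRCm38, the same assembly as mm10. Its coordinates are given 1-based.

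The test was tried on simulated data made from the real genes, with 200 of 13922 genes moved by a log2 change of 0.5, 1 or 2. For tamoxifen against vehicle in unwounded skin it recovered 58.2%, 88.1% and 100% of moved genes of these sizes, with 13 false calls. In wounded skin it recovered 61.2%, 85.1% and 100%, with 8 false calls, and for the interaction 29.9%, 77.6% and 97%, with 7 false calls. The simulated spread was drawn independently for each gene, and few genes were moved. In the real data genes move together and many more passed, so these shares and false calls are not error rates of the comparisons.

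Alternatives covered the pseudocount, the filter on low values, median-of-ratios and quantile scaling, library weights, robust variance moderation, fits of only the 2 groups compared, a replicate block, leaving out each library, a fold minimum of 2, and other tests of gene lists. Their effects are given after the report.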

Results

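Whole skin of K14CreERTM/LSL-SOX2 mice was profiled by RNA sequencing after topical tamoxifen (5 mg/ml in 200 µl) or vehicle. Skin was unwounded (day 0) or wounded (day 4). No unwounded skin of day 4 is among the samples, so differences by wound state are not separated from differences by day. The unwounded tamoxifen group held 3 libraries, and the unwounded vehicle group and both wounded sets held 4 each. Depth was 48927814 to 52246033 alignments per library in unwounded tamoxifen skin and 57271879 to 63992429 in unwounded vehicle skin. It was 39277860 to 67782635 in wounded set A and 61975321 to 75102345 in wounded set B. By the title of the series, the study asked whether SOX2 in the epidermis acts on wound healing through ligands of the epidermal growth factor receptor (EGFR) and the MEK/ERK pathway. No group received tamoxifen without the transgene, so an effect of tamoxifen itself is not separated from one of SOX2.

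The treatment of the wounded libraries is named differently in the sources. Wounded set A is recorded as tamoxifen and named vehicle in the gene tables, and wounded set B is recorded as vehicle and named tamoxifen in the gene tables. The deposited sheet of samples heads the records' names as the old group and the gene tables' names as the new group. Comparisons by the records therefore use the earlier names. Values below are given by set, and a direction of the treatment difference in wounded skin turns around with the naming. Comparisons under the gene tables' names were added after seeing the data.

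Sox2, the gene that the transgene carries (chromosome 3, 34650405 to 34652461, GENCODE M21), was at 2.89, 2.35 and 1.98 RPKM in the 3 unwounded tamoxifen libraries and at 2.57, 2.56, 2.04 and 1.85 RPKM in the 4 unwounded vehicle libraries. Wounded set A held 2.02, 2.18, 1.87 and 3.82 RPKM, and set B 2.07, 2.64, 2.55 and 2.27 RPKM. Group means were 2.4 ± 0.458 (SD, n = 3) with tamoxifen and 2.26 ± 0.365 (n = 4) with vehicle in unwounded skin, and 2.47 ± 0.908 and 2.38 ± 0.261 (n = 4 each) in sets A and B. In unwounded skin the difference was 0.07 ± 0.18 on the log2 scale (exact permutation p = 0.686, where 0.0571 is the smallest that 3 against 4 libraries allow). Between sets A and B it was 0.01 ± 0.17 (exact permutation p = 1.0, smallest possible 0.0286). Wounded against unwounded skin gave exact permutation p = 0.543 for set B against unwounded vehicle, 0.8 for set A against unwounded vehicle, and 1.0 for either set against unwounded tamoxifen. The interaction was -0.07 ± 0.25 (limma adjusted p = 0.82), and -0.08 ± 0.25 (0.821) under the gene tables' names. Sox2 therefore does not check the treatment names, and whether transcripts of the transgene were counted under this gene is not given in the sources used here. Reads assigned to a gfp sequence numbered 1 to 9 per library, with 13 in total in unwounded tamoxifen skin, 30 in unwounded vehicle skin, 20 in set A and 28 in set B. These totals are over unequal numbers of libraries and unequal depths. Per library they were 3 to 5 in unwounded tamoxifen and 5 to 9 in unwounded vehicle skin. In unwounded skin, where the names do not conflict, these values therefore do not show that the transgene was switched on.

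The libraries separated by group in a principal component analysis of log2(RPKM + 0.5). The first component (61.1% of the variance) placed unwounded tamoxifen libraries at 76.56 to 93.07, set B at 14.61 to 35.43, set A at -55.94 to -12.36 and unwounded vehicle libraries at -56.25 to -50.95. The second (26.3%) separated wounded libraries (15.57 to 42.37) from unwounded ones (-42.54 to -27). Within groups the correlation of 2 libraries across genes was lowest between replicates 2 and 4 of set A (0.958) and highest between replicates 3 and 4 of unwounded vehicle skin (0.996). Replicate 2 of set A lay at -12.36 on the first component, nearer to set B than the other 3 libraries of its set.

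**Figure D1:**
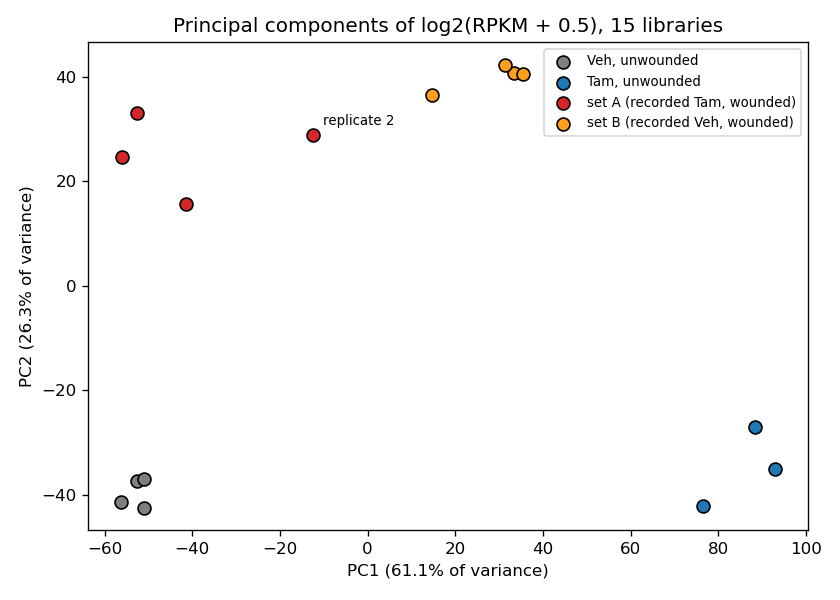
Principal components 1 (61.1% of the variance, horizontal axis) and 2 (26.3%, vertical axis) of log2(RPKM + 0.5) over 13922 genes, with 1 point per library and a colour per group. Unwounded tamoxifen libraries lie at 76.56 to 93.07 on the first component and unwounded vehicle libraries at -56.25 to -50.95, with set B at 14.61 to 35.43 and set A at -55.94 to -12.36.

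In unwounded skin, tamoxifen was compared with vehicle to find what the treatment changes without a wound. RPKM values are relative to all reads of a library of whole skin. A change per cell is therefore not separated from a change in the mix of cells, for rises and falls alike, here and in the later comparisons. Genes of hair shafts and follicles were higher by a median of 9.03 on the log2 scale, cell cycle genes and the EGFR ligand genes Tgfa, Areg and Hbegf were higher, and markers of macrophages, dendritic cells, T cells, fibroblasts, endothelial cells and muscle were lower. Krtap8-1, a keratin-associated protein of the hair shaft (chromosome 16, 89487379 to 89487952), was at 3601 ± 1391 RPKM (n = 3) with tamoxifen and 2.37 ± 0.861 RPKM (n = 4) with vehicle, a log2 difference of 10.25 ± 1.15. The EGFR ligand gene Tgfa (chromosome 6, 86195223 to 86275719) was at 22.8 ± 1.79 against 5.05 ± 0.542 RPKM, and Cd163, a macrophage scavenger receptor gene, at 10.2 ± 0.384 against 88.3 ± 19 RPKM. In all, 9662 of 13922 genes passed the test, 4835 higher and 4827 lower, and 2834 of them differed by at least 2-fold (1041 higher, 1793 lower). The libraries did not overlap for 9687 genes (69.6%, where chance gives 5.71%), of which 9130 passed.

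Among the EGFR ligands and receptors, 6 of 10 tested genes rose and 1 fell in unwounded tamoxifen skin, with the same counts adjusted over the list alone. Tgfa rose by 2.07 ± 0.15 (log2, adjusted p = 7.48e-08) and Areg, encoding amphiregulin, by 1.88 ± 0.24 (1.23e-05), from 2.16 ± 0.733 to 9.04 ± 1.09 RPKM. Hbegf rose by 0.93 ± 0.23 (0.00301), and the receptor genes Erbb2, Erbb3 and Egfr by 0.78, 0.72 and 0.28. The call of Egfr (adjusted p = 0.0156) was lost without replicate 2 of the tamoxifen group (0.0525). Egf fell (-0.86 ± 0.19, 0.00125). Ereg (0.02), Btc (0.46) and Epgn (-0.36) did not pass, and Erbb4 was under the filter on low values. The list as a set did not pass camera (median log2 difference 0.58, adjusted p = 0.102, and 0.483 with an estimated correlation). This list follows the study's own focus.

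**Figure D2:**
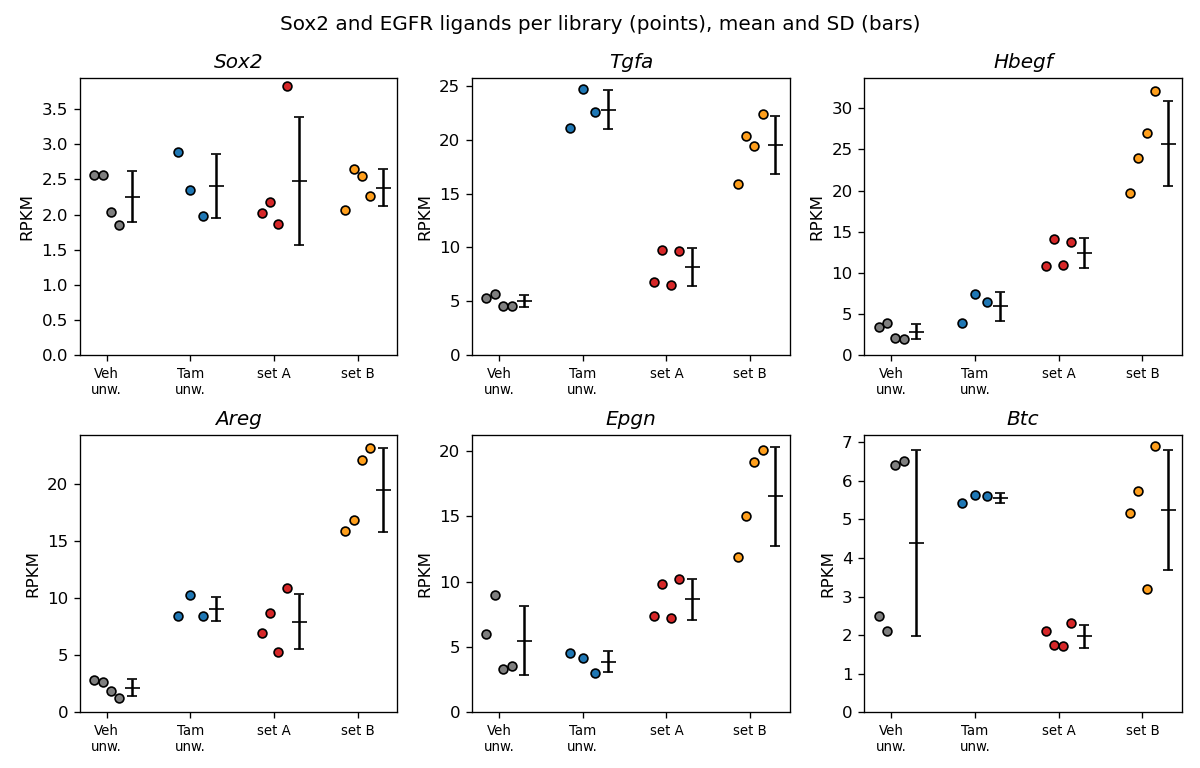
RPKM of EGFR ligand genes and Sox2 per library (points) with group means and SDs, for unwounded vehicle (n = 4), unwounded tamoxifen (n = 3), wounded set A and wounded set B (n = 4 each). Tgfa was at 22.8 ± 1.79 RPKM in unwounded tamoxifen skin against 5.05 ± 0.542 in unwounded vehicle skin, and at 19.5 ± 2.71 in set B against 8.2 ± 1.75 in set A, while Sox2 means lay between 2.26 and 2.47 RPKM.

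All 26 hair follicle and hair shaft genes rose with tamoxifen in unwounded skin (median log2 difference 9.03, camera adjusted p = 1.06e-09, and 0.388 with an estimated correlation). Krt71 and Krt25, keratins of the inner root sheath, rose by 10.23 ± 1.22 and 10.14 ± 1.26, Krtap7-1 by 10.05 ± 1.09 and Krt27 by 10.02 ± 1.17. Foxn1, a transcription factor gene of hair shaft differentiation, rose by 4.11 ± 0.24, from 1.38 ± 0.168 to 31.9 ± 3.56 RPKM. All 6 melanocyte markers rose (median 3.72, 0.00286, and 0.388 with an estimated correlation), among them the tyrosinase gene Tyr (3.19 ± 0.25). All 20 cell cycle genes rose (median 1.07, 3.21e-06, and 0.421 with an estimated correlation), with Ccnb1, encoding cyclin B1, at 21.6 ± 3.89 against 7.41 ± 1.37 RPKM.

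Of 19 MEK/ERK response genes, 11 rose with tamoxifen in unwounded skin and 0 fell, and 9 rose when adjusted over the list alone (camera adjusted p = 0.0401, and 0.483 with an estimated correlation). Dusp5, a phosphatase gene induced by ERK, rose by 2.15 ± 0.22, and the ephrin receptor genes Epha4 and Epha2 by 1.53 ± 0.15 and 1.52 ± 0.18. Without replicate 2 of the tamoxifen group the call of this list was lost (0.0677). Wound-activated keratinocyte genes went both ways, 7 up and 11 down of 23 (median -0.28, mean 0.01, adjusted p = 0.495), and the connexin genes Gjb2 (4.87 ± 0.28) and Gjb6 (3.75 ± 0.28) and Sprr1a (2.70 ± 0.32) were the 3 with the smallest p. In the deposited SOX2 target sheet, a list of unknown making that may have been picked on these samples and is no independent evidence of its direction, 36 of 71 genes rose and 19 fell (37 and 19 adjusted over the list alone; camera adjusted p = 0.0355, and 0.483 with an estimated correlation). Txnrd1, encoding a thioredoxin reductase, rose by 1.58 ± 0.08 there. Of 11 other Sox genes 6 rose and 4 fell (adjusted p = 0.469).

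Immune cell markers were lower in unwounded tamoxifen skin. Of 15 macrophage and monocyte markers 14 fell and 1, the arginase gene Arg1, rose (median -3.12, camera adjusted p = 3.73e-06), and Mrc1, encoding the mannose receptor, was at -3.21 ± 0.20 on the log2 scale. All 10 dendritic and Langerhans cell markers fell (median -2.02, 6.09e-05), with the class II antigen presentation gene H2-Aa at 147 ± 34.9 against 997 ± 82.7 RPKM, and so did all 7 T cell markers (median -1.35, 0.00286), with Cd4 at -2.93 ± 0.18. Of the inflammatory cytokine and chemokine genes 9 of 16 fell (8 adjusted over the list alone; 0.0152) and of the neutrophil markers 5 of 11 (0.0448). Mast cell markers did not pass as a list (7 of 8 fell and 1 rose, 0.0575). For the 5 of these lists that passed, the adjusted p = 0.388 to 0.483 with an estimated correlation. The call of the cytokine list was lost without replicate 2 of the tamoxifen group (0.052), and that of the neutrophil list without that library (0.0936) or replicate 4 of set A (0.0517) and with median-of-ratios scaling (0.0601).

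Stromal, glandular and muscle genes fell as well. Fibroblast markers (9 of 10 fell, median -1.25, adjusted p = 0.00126), endothelial markers (10 of 10, -1.03, 0.000225) and wound matrix genes (12 of 16, with 1 higher, or 13 and 1 adjusted over the list alone, -1.08, 0.0245) were lower, with the growth factor receptor gene Pdgfra at 6.33 ± 1.77 against 26.7 ± 3.81 RPKM. So were growth factors of the wound (9 of 13, 0.0174), Schwann cell markers (5 of 7, 1 up, 0.0277), sebaceous gland genes (8 of 10, 0.00437), skeletal muscle genes (13 of 15, 0.00924) and red blood cell genes (7 of 7, 0.0288). The red blood cell list lost its call without replicate 2 of the tamoxifen group (0.0719). All 5 oestrogen receptor targets fell (median -1.66, 0.00721). Tamoxifen acts on the oestrogen receptor, and the progesterone receptor gene Pgr, one of these targets, was at 0.0434 ± 0.0208 RPKM with tamoxifen, under the floor of 3 reads for a gene of 1 kb, and at 2.86 ± 1.29 RPKM with vehicle. These 9 lists had an adjusted p = 0.388 to 0.522 with an estimated correlation. Adipocyte markers (1 up and 6 down of 11, 0.135), Merkel cell markers (4 up and 1 down of 6, 0.159) and basal keratinocyte markers (1 up and 4 down of 9, 0.495) did not pass. Neither did differentiated keratinocyte markers (7 up and 8 down of 17, or 8 and 8 adjusted over the list alone, median 0.28, mean -0.05, 0.967), epithelial antimicrobial and alarmin genes (2 up and 4 down of 11, median -0.36, mean 0.14, 0.828) or oral epithelium-associated genes (2 up and 1 down of 5, 0.495, with a median of -0.003 and a mean of 1.70).

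The 5 largest falls in unwounded tamoxifen skin were in Klk1, a kallikrein protease gene (-6.50 ± 0.83; 0.126 ± 0.0199 against 88.4 ± 79.9 RPKM), Rnase2a (-5.71 ± 0.35), Sprr2a3, a gene of the cornified envelope (-5.59 ± 0.41), Stfa1 (-5.18 ± 0.53) and Klk1b21 (-5.12 ± 0.82). Without replicate 4 of the tamoxifen group Stfa1 was at -4.54, and Klk1b21 was at -5.89 without replicate 2 and -4.52 without replicate 3 of the vehicle group. These genes have close paralogs, so their values are uncertain where reads were split between copies.

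Between the wounded sets, set A (recorded as tamoxifen) was compared with set B (recorded as vehicle). Hair genes, EGFR ligands and wound-activated keratinocyte genes were lower in set A, and markers of T cells, dendritic cells, macrophages, endothelial cells and sebaceous glands were higher. Krtap8-1 was at 48.3 ± 91.3 RPKM in set A and 839 ± 252 RPKM in set B (n = 4 each), Tgfa at 8.2 ± 1.75 against 19.5 ± 2.71 RPKM, and Cd163 at 135 ± 6.61 against 54.1 ± 12.6 RPKM. Replicate 2 of set A held Krtap8-1 at 185 RPKM, and without it the mean of the set was 2.64 ± 1.75 (n = 3). By the records these are differences of tamoxifen from vehicle, and by the gene tables' names each has the opposite sign. In all, 4328 genes passed, 2169 higher and 2159 lower in set A, and 660 of them differed by at least 2-fold (291 higher, 369 lower). With library weights the count was 7041. The sets did not overlap for 3938 genes (28.3%, where chance gives 2.86%), of which 3404 passed.

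Of 10 EGFR ligands and receptors 7 were lower in set A and 0 higher, with the same counts adjusted over the list alone (median log2 difference -0.68, camera adjusted p = 0.000973, and 0.232 with an estimated correlation). Areg differed by -1.27 ± 0.22 (log2) (adjusted p = 0.000947), Tgfa by -1.21 ± 0.14 (4.82e-05) and Hbegf by -1.01 ± 0.22 (0.00338), with Areg at 7.92 ± 2.4 RPKM in set A and 19.5 ± 3.66 in set B. Btc, Erbb2, Epgn and Erbb3 also passed. Erbb2 (0.0127) did not with only the 2 sets in the fit (0.0553), and neither did Erbb3 (0.0793). Epgn (0.0206) lost its call without replicate 1 (0.0592) or 3 (0.0568) of set A or replicate 3 (0.0571) or 4 (0.0661) of set B. Erbb3 (0.0295) lost it without replicate 1 (0.0925), 2 (0.0556) or 3 (0.0546) of set A or 2 (0.0531), 3 (0.0761) or 4 (0.0878) of set B. Of 19 MEK/ERK response genes 10 were lower in set A and 0 higher (12 lower adjusted over the list alone; 0.00027, and 0.26 with an estimated correlation), with Dusp6 at -0.65 ± 0.12.

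Wound-activated keratinocyte genes were lower in set A for 17 of 23 members and higher for 0 (18 lower adjusted over the list alone; median -0.82, camera adjusted p = 2.08e-07, and 0.232 with an estimated correlation). Lama3 and Lamb3, which encode laminin chains, differed by -1.02 ± 0.10 and -0.83 ± 0.08. All 26 hair genes were lower (median -5.20, 5.18e-15, and 0.232 with an estimated correlation), and so were Krtap7-1 (-6.64 ± 1.01), Krtap22-2 (-6.59 ± 1.03), Krtap4-1 (-6.57 ± 0.74) and Krtap1-5 (-6.55 ± 0.94). Without replicate 2 of set A the median of the hair list was -6.60, and these 4 genes were at -8.06, -7.97, -7.37 and -7.85. Krtap7-1 and Krtap22-2 were at -6.04 and -5.98 without replicate 1 of set A, and at -5.98 and -6.00, with Krtap1-5 at -5.84, without replicate 4. The mean log2(RPKM + 0.5) over the hair genes was 4.8 in replicate 2 of set A and 0.528 to 1.17 in the other 3 libraries of the set. Basal keratinocyte markers (5 of 9, or 6 adjusted over the list alone, 0.0153) and the SOX2 target sheet (25 lower and 8 higher of 71, or 26 and 8, 0.000973) were lower, at 0.356 and 0.26 with an estimated correlation. None of the 20 cell cycle genes passed (median -0.07, 0.346), with Mcm2 at -0.20 ± 0.10.

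Higher in set A were T cell markers (6 of 7, camera adjusted p = 1.33e-05), dendritic and Langerhans cell markers (9 of 10, 1.33e-05), macrophage and monocyte markers (8 of 15, or 9 adjusted over the list alone, 0.000243) and mast cell markers (4 of 8, or 6, 0.0282). So were endothelial markers (9 of 10, or 10, 7.88e-06), fibroblast markers (5 of 10, 0.0155), red blood cell genes (7 of 7, 0.000311), sebaceous gland genes (8 of 10, 0.000397), Schwann cell markers (5 of 7, or 6, 0.000973) and oestrogen receptor targets (3 of 5, or 4, 0.0282). All 10 lists had an adjusted p = 0.232 to 0.494 with an estimated correlation. Cd4 was at 5.58 ± 0.486 against 1.27 ± 0.284 RPKM and Pgr at 0.749 ± 0.391 against 0.0103 ± 0.00593 RPKM, the value of set B being under the floor of 3 reads for a gene of 1 kb. Neutrophil markers (2 higher and 1 lower of 11, 0.67) and cytokines and chemokines (1 higher and 4 lower of 16, 0.346) did not pass. The mast cell call was lost without replicate 2 (0.062) or 4 (0.0949) of set A, and the fibroblast call without replicate 3 of set A (0.0662). The 5 genes with the largest excess in set A were H2-Q2 (4.94 ± 0.23), a class I histocompatibility gene (chromosome 17, 35342242 to 35346762), BC018473 (4.68 ± 0.12), Sprr2b (3.71 ± 0.42), H2-Ea-ps (3.30 ± 0.10), annotated as a polymorphic pseudogene (chromosome 17, 34341959 to 34344645), and Klk1 (3.16 ± 0.77). BC018473 is annotated as antisense, and since the use of strand in the counting is not given, its reads cannot be told apart from those of the opposite strand.

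The treatment difference by the sample records ran opposite ways in unwounded and wounded skin. Across 13922 genes the correlation of both log2 differences was -0.853 (Pearson) and -0.715 (Spearman), between comparisons that share no library, and genes are not independent replicates. Of 3755 genes that passed in both, 143 had the same sign and 3612 opposite signs. With the gene tables' names for the wounded sets, the signs of the wounded comparison, and with them these counts and correlations, turn around.

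**Figure D3:**
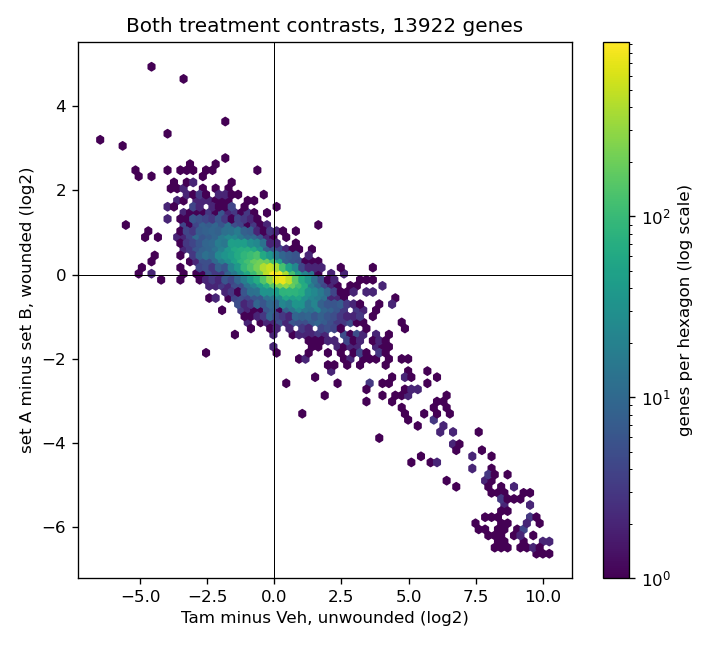
Log2 difference of tamoxifen from vehicle in unwounded skin (horizontal axis) against that of wounded set A from set B (vertical axis) for 13922 genes. Genes are binned into hexagons, coloured by the number of genes in each on a log scale. Of 3755 genes that passed in both comparisons 3612 lie in the quadrants of opposite sign, and the Pearson correlation across genes is -0.853.

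Wounding was first compared against unwounded vehicle skin, with set B as the wounded vehicle group by the records and set A as that group by the gene tables. Here and below wounding is confounded with day, since all wounded libraries are of day 4 and all unwounded ones of day 0. In both, cytokines, antimicrobial genes, neutrophil markers, wound-activated keratinocyte genes and cell cycle genes were higher, and muscle, adipocyte, sebaceous and red blood cell genes were lower. Saa3, an acute phase gene, rose from 1.99 ± 0.21 RPKM in unwounded vehicle skin to 1086 ± 347 in set B and 2027 ± 1073 in set A (n = 4 each). For set B 8244 genes passed (4269 higher, 3975 lower), and for set A 5541 (2847 higher, 2694 lower). Of these, 1862 (878 higher, 984 lower) and 954 (479 higher, 475 lower) differed by at least 2-fold. The libraries did not overlap for 8503 (61.1%) and 4978 (35.8%) genes, where chance gives 2.86%, and 7752 and 4504 of these passed.

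In set B against unwounded vehicle skin 22 of 23 wound-activated keratinocyte genes rose (median 2.85, camera adjusted p = 5.57e-13, and 0.104 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase gene, higher by 2.85 ± 0.13. Of 16 cytokine and chemokine genes 13 rose and 1 fell (2.85e-07), among them the neutrophil attractant gene Cxcl2 (6.34 ± 0.19). All 11 antimicrobial and alarmin genes (2.09e-06; Defb14 3.77 ± 0.22), 10 of 11 neutrophil markers (6.67e-05) and 20 of 20 cell cycle genes (4.84e-08; Ccnb1 1.43 ± 0.12) rose. So did 23 of 26 hair genes (24, with 1 lower, adjusted over the list alone; median 6.59, 8.9e-08), with Krt25 (8.21 ± 1.17), Krtap8-1 (8.18 ± 1.06), Krt71 (8.08 ± 1.13) and Krtap22-2 (8.07 ± 1.03) next to Saa3 (8.72 ± 0.39) as the 5 largest rises. EGFR ligands and receptors rose for 7 of 10 and fell for 1 (8 and 1 adjusted over the list alone; 0.0101), with Hbegf higher by 2.97 ± 0.22, Areg by 2.94 ± 0.22 and Tgfa by 1.85 ± 0.14. MEK/ERK response genes rose for 10 of 19 and fell for 1 (0.00706), with the AP-1 subunit gene Fosl1 higher by 3.09 ± 0.28. Wound matrix genes rose for 8 of 16 and fell for 2 (0.039), with the tenascin C gene Tnc higher by 4.57 ± 0.28, and the SOX2 target sheet for 36 of 71, with 19 lower (0.039). With an estimated correlation these lists after the first had an adjusted p = 0.228 to 0.536. The matrix call was lost without replicate 2 of unwounded tamoxifen (0.0505), replicate 2 of unwounded vehicle (0.0612) or replicate 1 (0.0543) or 3 (0.0536) of set B, and in a rank-based test (0.0614). The call of the target sheet was lost without replicate 4 of unwounded vehicle skin (0.0542).

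Lower in set B than in unwounded vehicle skin were skeletal muscle genes (14 of 15, camera adjusted p = 3.08e-05), adipocyte markers (10 of 11, 0.00031), T cell markers (7 of 7, 0.000147), dendritic and Langerhans cell markers (9 of 10, 6.67e-05) and red blood cell genes (7 of 7, 6.23e-05). So were sebaceous gland genes (9 of 10, 3.08e-05), Schwann cell markers (7 of 7, 6.47e-05), fibroblast markers (5 of 10, 0.039) and oestrogen receptor targets (4 of 5, 0.0132). The adjusted p of these 9 lists was 0.228 to 0.498 with an estimated correlation. The fibroblast call was lost without replicate 4 of set A (0.0537), replicate 1 (0.0534) or 3 (0.0515) of unwounded vehicle skin or replicate 4 of set B (0.0542). The 5 largest falls were Retnla, a gene of alternatively activated macrophages (-5.67 ± 0.53), Rnase2a (-5.61 ± 0.33), Klk1b21 (-5.10 ± 0.76), Klk1 (-5.00 ± 0.77) and Klk1b24 (-4.99 ± 0.73). Without replicate 2 of unwounded vehicle skin Klk1b21 was at -5.88 and Klk1b24 at -5.64, and without replicate 3 Klk1b21 was at -4.51.

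In set A against unwounded vehicle skin 21 of 23 wound-activated keratinocyte genes rose (22 adjusted over the list alone; median 1.86, camera adjusted p = 4.58e-14, and 0.0801 with an estimated correlation), with Gjb2 higher by 3.65 ± 0.26. Cytokines and chemokines (12 of 16, 5.42e-11), antimicrobial genes (11 of 11, 7.17e-10), neutrophil markers (11 of 11, 2.46e-08), cell cycle genes (19 of 20, or 20 adjusted over the list alone, 3.65e-11), wound matrix genes (8 of 16, 0.0012) and endothelial markers (6 of 10, 0.00632) rose. Muscle genes (14 of 15, 1.86e-06), adipocyte markers (9 of 11, 0.000327), Schwann cell markers (7 of 7, 0.000257), red blood cell genes (7 of 7, 0.000397), sebaceous gland genes (7 of 10, or 8, 0.00116), dendritic and Langerhans cell markers (7 of 10, or 7 with 1 higher, 0.0139) and oestrogen receptor targets (4 of 5, with 1 higher, 0.0471) fell. With an estimated correlation all of these had an adjusted p = 0.0839 to 0.545. Hair genes did not pass as a list (Foxn1 up, Lhx2 and Gata3 down of 26, or 0 up and 2 down adjusted over the list alone, 0.461), nor did EGFR ligands and receptors (4 up and 2 down of 10, 0.305) or MEK/ERK response genes (7 up and 3 down of 19, 0.342). Hbegf rose by 1.97 ± 0.22, Areg by 1.66 ± 0.22 and Tgfa by 0.63 ± 0.14. Epgn (0.0475) lost its call in 12 of 15 leave-outs, all but those of replicate 4 of unwounded tamoxifen, 2 of unwounded vehicle and 1 of set B (0.0518 to 0.145). Btc (0.0374) lost it without replicate 1 (0.059), 2 (0.0773) or 3 (0.0815) of set A or 3 (0.119) or 4 (0.121) of unwounded vehicle skin. With no filter on low values neither passed (0.0735 and 0.0597), nor with only the 2 groups in the fit (0.0904 and 0.0833). The oestrogen receptor call was lost without replicate 3 of unwounded tamoxifen (0.0541), 3 of unwounded vehicle (0.0555), 2 (0.0758) or 4 (0.0983) of set A or 2 (0.0502) or 4 (0.0529) of set B, with median-of-ratios scaling (0.0543) and in a rank-based test (0.0741). The largest rises were Saa3 (9.51 ± 0.39), the chemokine genes Cxcl3 (6.21 ± 0.33), Cxcl2 (6.17 ± 0.19) and Cxcl5 (6.16 ± 0.34), and Stfa2l1 (5.19 ± 0.28). The largest falls were Mstn, encoding myostatin (-3.85 ± 0.53), Retnla (-3.58 ± 0.53), Apobec2 (-3.57 ± 0.40), Pvalb (-3.46 ± 0.59) and Dhrs7c (-3.28 ± 0.44), of which Mstn, Apobec2 and Pvalb are expressed in muscle.

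Wounding was then compared against unwounded tamoxifen skin, with set A as the wounded tamoxifen group by the records and set B as that group by the gene tables. In both, cytokine, neutrophil, macrophage, matrix and wound-activated keratinocyte genes were higher and melanocyte and hair genes were lower. Krt6b, a keratin of activated keratinocytes, rose from 4.13 ± 1.65 RPKM (n = 3) to 1888 ± 169 in set A and 1992 ± 303 in set B (n = 4 each). For set A 9107 genes passed (4356 higher, 4751 lower), and for set B 7633 (3610 higher, 4023 lower). Of these, 2778 (1741 higher, 1037 lower) and 1703 (1164 higher, 539 lower) differed by at least 2-fold. The libraries did not overlap for 8222 (59.1%) and 8074 (58.0%) genes, where chance gives 5.71%, and 8025 and 7149 of these passed.

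In set A against unwounded tamoxifen skin all 16 cytokines and chemokines (median 3.44, camera adjusted p = 3.91e-09), 15 of 15 macrophage and monocyte markers (1.7e-08) and 11 of 11 neutrophil markers (3.67e-06) rose, with Ccl4 higher by 5.19 ± 0.17 and Cd163 by 3.66 ± 0.17. So did wound-activated keratinocyte genes (18 of 23, 4 lower, 1.65e-05; Il33 4.03 ± 0.23), wound matrix genes (15 of 16, or 16 adjusted over the list alone, 1.04e-05; Timp1 5.43 ± 0.31), endothelial markers (10 of 10, 9.25e-06), dendritic and Langerhans cell markers (10 of 10, 0.000351) and antimicrobial genes (9 of 11, 1 lower, 0.000582). Fibroblast markers (8 of 10, 0.00303), growth factors of the wound (10 of 13, with 1 lower adjusted over the list alone, 0.00492), T cell markers (6 of 7, 0.00876) and mast cell markers (6 of 8, 1 lower, 0.0498) rose too. All 26 hair genes (-7.72, 1.92e-09), all 6 melanocyte markers (0.00283), 4 of 6 Merkel cell markers (0.038) and 40 of 71 genes of the SOX2 target sheet, with 14 higher, or 40 and 15 adjusted over the list alone (0.0358), fell. All 16 lists had an adjusted p = 0.259 to 0.599 with an estimated correlation. The mast cell call was lost when any library of unwounded tamoxifen skin or set B, or replicate 2 or 4 of set A, was left out (0.0501 to 0.0779), with median-of-ratios scaling (0.055) and in a rank-based test (0.057). The Merkel cell call was lost without replicate 4 of set A (0.0514). The median of the hair list was -8.97 without replicate 2 of set A.

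EGFR ligands and receptors went both ways in set A against unwounded tamoxifen skin, 2 up and 4 down of 10 (camera adjusted p = 0.475). Hbegf (1.04 ± 0.23) and Epgn (1.06 ± 0.28) rose, and Tgfa (-1.44 ± 0.15), Btc (-1.30 ± 0.32), Erbb2 (-0.86 ± 0.13) and Erbb3 (-0.46 ± 0.16) fell. The call of Erbb3 was lost without replicate 3 (0.0793) or 4 (0.0568) of unwounded tamoxifen skin or replicate 1 of set A (0.0674), and with only the 2 groups in the fit (0.066). Of MEK/ERK response genes 3 rose and 11 fell of 19 (0.183), with Epha4 at -1.11 ± 0.15 and Fosl1 at 1.82 ± 0.30. Of 20 cell cycle genes 3 passed and none adjusted over the list alone (0.557): Cenpf (-0.45 ± 0.13), Mcm2 (-0.28 ± 0.11) and Pcna (-0.21 ± 0.09). Mcm2 lost its call without replicate 2 (0.215) or 3 (0.0844) of unwounded tamoxifen skin or 1 (0.0961) or 3 (0.102) of set A, and Pcna in every leave-out but those of replicate 4 of unwounded tamoxifen and replicate 2 of set A (0.0502 to 0.305). Both also lost it with no filter on low values (0.0514 and 0.0597) and with only the 2 groups in the fit (0.137 and 0.163), and Pcna with 5 further settings, up to 0.13 with quantile normalization. The largest rises were Krt6b (8.73 ± 0.50), Saa3 (8.65 ± 0.42), Stfa1 (8.48 ± 0.53), BC100530 (7.87 ± 0.56) and Sprr2d (7.85 ± 0.38). The largest falls were Krtap8-1 (-8.71 ± 1.15), Krtap7-1 (-8.63 ± 1.09), Krt71 (-8.48 ± 1.22), Krtap15 (-8.43 ± 0.98) and Krtap1-5 (-8.37 ± 1.02). These 5 genes, without replicate 2 of set A, were at -10.21, -10.05, -10.08, -9.71 and -9.66. Without replicate 4 Krtap8-1, Krtap7-1, Krt71 and Krtap1-5 were at -7.99, -7.98, -7.79 and -7.65, and without replicate 1 Krtap7-1 and Krt71 were at -8.03 and -7.66. Stfa1 was at 7.83 without replicate 4 of unwounded tamoxifen skin.

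In set B against unwounded tamoxifen skin all 16 cytokines and chemokines rose (median 3.41, camera adjusted p = 1.8e-12), as did 18 of 23 wound-activated keratinocyte genes (3.05, 4.68e-12), both at 0.0714 with an estimated correlation. Macrophage and monocyte markers (15 of 15, 2.69e-09), neutrophil markers (10 of 11, 2.57e-07), wound matrix genes (12 of 16, or 14 adjusted over the list alone, 8.97e-07), antimicrobial genes (8 of 11, 1 lower, or 10 and 1, 3.33e-05), endothelial markers (8 of 10, 0.000279), growth factors (10 of 13, 1 lower, 0.0012), fibroblast markers (6 of 10, 0.0159) and basal keratinocyte markers (6 of 9, 1 lower, 0.0315) rose. Hair genes (15 of 26, or 18 adjusted over the list alone, 0.000279), melanocyte markers (6 of 6, 0.00106), red blood cell genes (7 of 7, 0.0122) and adipocyte markers (7 of 11, 0.0391) fell. These 12 lists had an adjusted p = 0.177 to 0.697 with an estimated correlation. The adipocyte call was lost without replicate 2 of unwounded tamoxifen (0.104) or 4 of set B (0.0684), and the basal keratinocyte call without replicate 2 of unwounded tamoxifen (0.0541). EGFR ligands and receptors did not pass as a list (3 up and 1 down of 10, 0.439). Hbegf rose by 2.05 ± 0.23, Epgn by 1.94 ± 0.28 and Areg by 1.05 ± 0.24, while Tgfa (-0.23 ± 0.15) did not pass. Erbb2 (-0.41 ± 0.13) lost its call without replicate 2 of unwounded tamoxifen (0.0525). MEK/ERK response genes rose for 4 and fell for 3 of 19 (median -0.10, mean 0.07, 0.698). In the cell cycle list (0.957) Mcm4 (0.30 ± 0.11) and Cenpf (-0.34 ± 0.13) passed of 20, and 0 adjusted over the list alone. Mcm4 lost its call without replicate 3 (0.076) or 4 (0.158) of unwounded tamoxifen or 2 (0.0725) or 4 (0.0544) of set B, and Cenpf without replicate 2 (0.187) or 3 (0.053) of unwounded tamoxifen or 1 (0.0836), 2 (0.0643) or 4 (0.0783) of set B. With only the 2 groups in the fit neither passed (0.0589 and 0.0639), nor did Cenpf with no filter on low values (0.0514). The largest rises were Krt6b (8.79 ± 0.50), Stfa1 (8.49 ± 0.53), Saa3 (7.85 ± 0.42), BC100530 (7.48 ± 0.56) and Cxcl3 (7.09 ± 0.36). The largest falls were Mlana (-3.57 ± 0.60), Ptgds (-3.51 ± 0.42), Dct (-3.44 ± 0.44), Trpm1 (-3.43 ± 0.45) and Pmel (-3.42 ± 0.48), of which Mlana, Dct, Trpm1 and Pmel are expressed in melanocytes. Stfa1 was at 7.84 without replicate 4 of unwounded tamoxifen skin.

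Wound responses were compared across genes between pairs that share no library. By the records (set B against unwounded vehicle and set A against unwounded tamoxifen) the correlation of log2 differences was -0.347 (Pearson) and -0.231 (Spearman), with 1880 of 5620 genes that passed in both of the same sign and 3740 of opposite sign. By the gene tables' names it was 0.525 and 0.356, with 2658 of 3336 genes of the same sign and 678 of opposite sign.

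The interaction tests whether the wound response differs between the treatments. It equals the treatment difference in wounded skin less that in unwounded skin. Its size as well as its sign therefore depends on the naming of the wounded sets. Under the gene tables' names, given below, 5565 genes passed and the hair list had a median of -3.31. If the records exchange the names, the values by the records add up both treatment differences and are no measure of a wound response. By the records 9538 genes passed, 4722 with a higher and 4816 with a lower response in tamoxifen skin, and 4133 of these differed by at least 2-fold (2501 higher, 1632 lower). All 26 hair genes responded lower (median -14.38, camera adjusted p = 4.85e-11), with Krtap8-1 at -16.88 ± 1.56, Krtap7-1 at -16.69 ± 1.49, Krt71 at -16.56 ± 1.67, Krt25 at -16.47 ± 1.72 and Krtap22-2 at -16.42 ± 1.51. Cell cycle genes (20 of 20, 2.91e-05; Ccnb1 -1.60 ± 0.18), melanocyte markers (6 of 6, 0.00639), EGFR ligands and receptors (7 of 10, 1 higher, 0.0217), MEK/ERK response genes (14 of 19, or 15 adjusted over the list alone, 0.00634) and the SOX2 target sheet (40 of 71, 16 higher, 0.0111) also responded lower. Tgfa was at -3.28 ± 0.20 and Areg at -3.16 ± 0.33. Macrophage and monocyte markers (14 of 15, 1 lower, 9.38e-06; Cd163 4.36 ± 0.23), dendritic and Langerhans cell markers (10 of 10, 2.91e-05), T cell markers (7 of 7, 0.000676), mast cell markers (7 of 8, 1 lower, 0.0356), endothelial markers (10 of 10, 5.35e-05) and fibroblast markers (9 of 10, 0.00169) responded higher. So did sebaceous gland (8 of 10, or 9 adjusted over the list alone, 0.00185), Schwann cell (6 of 7, 0.0098), red blood cell (7 of 7, 0.00634), skeletal muscle (13 of 15, 0.0122) and oestrogen receptor (5 of 5, 0.00639) genes. With an estimated correlation all 17 lists had an adjusted p = 0.36 to 0.546. Klk1 (9.66 ± 1.13), H2-Q2 (9.50 ± 0.33), Rnase2a (8.79 ± 0.48), BC018473 (8.01 ± 0.18) and Klk1b21 (7.64 ± 1.12) had the largest differences upwards. Wound-activated keratinocyte genes did not pass as a list (5 higher and 12 lower of 23, 0.114). Without replicate 2 of set A the hair list had a median of -15.65, and Krtap8-1, Krtap7-1, Krt71, Krt25 and Krtap22-2 were at -18.39, -18.11, -18.16, -18.13 and -17.80. Without replicate 4 these 5 genes were at -16.16, -16.03, -15.87, -15.70 and -15.83. Without replicate 1 the median was -13.76, and Krtap7-1, Krt71, Krt25 and Krtap22-2 were at -16.09, -15.74, -15.65 and -15.81. Krtap22-2 was at -17.06 without replicate 2 of unwounded tamoxifen skin, and Klk1b21 at 8.41 and 7.04 without replicates 2 and 3 of unwounded vehicle skin.

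Under the gene tables' names 5565 genes passed the interaction, 2749 with a higher and 2816 with a lower response in tamoxifen skin, and 1475 of these differed by at least 2-fold (965 higher, 510 lower). Wound-activated keratinocyte genes (15 of 23, 2 lower, or 15 and 3 adjusted over the list alone; median 1.24, camera adjusted p = 0.00142) responded higher, with Plaur, the urokinase receptor gene, at 2.11 ± 0.24. So did cytokines and chemokines (9 of 16, 0.000504), macrophage and monocyte markers (13 of 15, 1 lower, or 14 and 1, 5.41e-07), dendritic and Langerhans cell markers (9 of 10, or 10, 0.00103), fibroblast (8 of 10, or 9, 0.0018) and endothelial markers (6 of 10, or 7, 0.018), growth factors (7 of 13, or 8, 0.00307), wound matrix genes (8 of 16, or 8 with 1 lower, 0.00923) and oestrogen receptor targets (4 of 5, 0.0114). Neutrophil markers (5 of 11, 1 lower, or 7 and 1, 0.0366), basal keratinocyte markers (4 of 9, 1 lower, 0.0437) and muscle genes (1 of 15, or 0, 0.0192) passed as lists too. Cell cycle genes (17 of 20, 7.83e-08; Ccnb2 -1.37 ± 0.18), melanocyte markers (6 of 6, 0.000504) and hair genes (16 of 26, or 21, 5.77e-05) responded lower. With an estimated correlation all 15 lists had an adjusted p = 0.447 to 0.677. The neutrophil call was lost without replicate 2 of unwounded tamoxifen (0.0949), 1 (0.0814) or 4 (0.095) of set A or 3 of set B (0.0677). The basal keratinocyte call was lost without replicate 2 of unwounded tamoxifen (0.0949), 1 (0.0722), 2 (0.0522) or 3 (0.103) of set A, 2 of unwounded vehicle (0.0592) or 4 of set B (0.0642). The muscle call was lost without replicate 4 of set A (0.0807) and with fry (0.138). The muscle gene that passed, Mylpf (1.66 ± 0.58), lost its call without replicate 3 (0.0906) or 4 (0.081) of unwounded tamoxifen, 3 (0.0525) or 4 (0.0542) of set A, 1 (0.0614) or 2 (0.0625) of unwounded vehicle or 1 of set B (0.0671), and with no filter on low values (0.0596). Mylpf, and Foxn1, Lhx2 and Gata3 in set A against unwounded vehicle skin, were named after their values were seen. The median of the hair list was -3.31, and -2.18 without replicate 2 of set A.

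For single genes under the gene tables' names, the interaction of Tgfa was -0.86 ± 0.20 (adjusted p = 0.00447) and that of Epgn 1.24 ± 0.39 (0.0208), and the other 8 EGFR ligands and receptors did not pass (list median -0.03, mean 0.10, 0.92). Epgn lost its call without replicate 4 of unwounded tamoxifen (0.0605). MEK/ERK response genes had 1 up and 4 down of 19, or 0 and 4 adjusted over the list alone (0.777), with Dusp5 at -1.20 ± 0.30. The largest differences upwards were Stfa1 (5.19 ± 0.72), Pyy, encoding peptide YY (4.88 ± 0.68), Sprr2a2 and Sprr2a1 (4.62 ± 0.56 each) and Sprr2a3 (4.43 ± 0.55). Sprr2a1 and Sprr2a2 have identical values in every library and are near-identical copies, so they are uncertain. The largest downwards were Krt31 (-4.31 ± 1.43), Krt85 (-4.22 ± 1.39), Krt33a (-4.07 ± 1.47), Mlana (-3.99 ± 0.81) and Krt83 (-3.98 ± 1.38). Krt31 lost its call without replicate 3 (0.051) or 4 (0.0606) of unwounded tamoxifen or 1 of set B (0.0544), and Krt85 without replicate 4 of unwounded tamoxifen (0.0565) or 1 of set B (0.0526). Krt33a lost it without any 1 library outside set A (0.0514 to 0.0846), and Krt83 without replicate 3 (0.0635) or 4 (0.0776) of unwounded tamoxifen, 1 (0.0569), 2 (0.0505) or 3 (0.0568) of unwounded vehicle or 1 of set B (0.0657). With a pseudocount of 0.1 Krt33a (0.0606) and Krt83 (0.0547) did not pass, nor with no filter on low values (0.0688 and 0.0593). Without replicate 2 of set A Krt31, Krt85, Krt33a and Krt83 kept their calls at -2.90, -2.84, -2.63 and -2.63. Krt85 was at -4.86 without replicate 1 and Krt33a at -4.67 without replicate 4 of set A, and Stfa1 was at 4.54 without replicate 4 of unwounded tamoxifen skin.

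Some further lists that did not pass had a median and a mean of opposite sign. These were differentiated keratinocyte markers in set A (-0.15 and 0.02) and set B (-0.13 and 0.08) against unwounded tamoxifen skin, and T cell markers in the latter (-0.10 and 0.12). In the interaction they were antimicrobial genes by the records (0.18 and -0.06) and oral epithelium-associated genes under the gene tables' names (0.07 and -0.67).

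The authors' deposited table of contrasts, in which the wounded sets carry the gene tables' names, has 13195 genes with a q under 0.05 for tamoxifen against vehicle in unwounded skin and 5629 in wounded skin. It has 7456 for wounded against unwounded vehicle skin and 10363 for wounded against unwounded tamoxifen skin. Of the genes tested here, 9661, 4276, 5517 and 7610 passed in both and all of these had the same direction as here for the same libraries. In the authors' deposited table the ratio for Tgfa was 4.45 (q = 7.61e-07) in unwounded and 2.39 (q = 0.000311) in wounded skin, and that for Sox2 1.06 (q = 0.27) and 1.0 (q = 0.542).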

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

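In this part the interaction by the sample records and the 2 tests of RNA mixed into replicate 2 of wounded set A were chosen before their results were seen. The interaction under the gene tables' names and the other tests of explanations were chosen after.

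The interaction of treatment and wounding passed for 9538 genes by the sample records. The widest differences were in Klk1 (9.66 on the log2 scale), H2-Q2 (9.50), Rnase2a (8.79), BC018473 (8.01) and Klk1b21 (7.64), and in Krtap8-1 (-16.88), Krtap7-1 (-16.69), Krt71 (-16.56), Krt25 (-16.47) and Krtap22-2 (-16.42). Under the gene tables' names 5565 genes passed. The widest differences were then in Stfa1 (5.19), Pyy (4.88), Sprr2a2 and Sprr2a1 (4.62 each) and Sprr2a3 (4.43), and in Krt31 (-4.31), Krt85 (-4.22), Krt33a (-4.07), Mlana (-3.99) and Krt83 (-3.98). The values of Krt31, Krt33a, Krt83 and Krt85 rest on calls that leaving out single libraries ends, and these and the other keratin genes, the keratin-associated genes, Klk1b21 and Stfa1 move in size without single libraries, with values in the report.

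The treatment difference by the sample records ran opposite ways in unwounded and wounded skin. A candidate explanation is that the treatment names of the 2 wounded sets are exchanged in the sample records. The gene tables give the other names, which the sheet of samples heads as the new group. The submitters' later naming thus goes with this explanation. In all, 8 of 8 wounded libraries deviated from the mean of the 8 against their recorded treatment. The sign of the difference between the sets nearly fixes this count, so that it decides nothing. Mice of 2 genetic backgrounds cannot be told apart from exchanged names. One would lie behind unwounded tamoxifen and set B, the other behind unwounded vehicle and set A. In this pairing 9 genes were below 0.5 RPKM in every library of one pair of groups and at least 2 RPKM in every library of the other. By the same thresholds 0 genes followed the recorded treatment and 14 the wound state. These thresholds were set after H2-Q2, H2-Ea-ps and BC018473 had been seen, 4 of the 9 (Krt90, Krtap4-13, Gm11564 and 2310061N02Rik) follow the hair genes or lie beside them, and of the other 5 H2-Q2, H2-Ea-ps, BC018473 and Rnase2a had been named in a comparison and Gm9199 had not. Tamoxifen treatment acting the opposite way in wounded skin also stays open, since 3612 genes that passed in both comparisons with opposite signs would be seen under either, and if the backgrounds differ, treatment may be confounded with them under both namings.

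Hair follicle genes led the rise in unwounded tamoxifen skin. A shift in the scale of the libraries moves all genes of a library alike. Genes that lead the others already forbid it as the whole cause, so the following values restate the pattern and are no separate test. The hair list had a median of 9.033 on the log2 scale, and 95% of the 13896 tested genes outside it lay between -2.182 and 1.894 with a median of 0.0. A larger epithelial share of the tissue piece is argued against as the whole cause, since basal keratinocyte markers did not rise as a list (median -0.304). The rule written for it, a median near the 9.033 of the hair list, came after the pattern was seen. It could hardly be met, so it decides nothing. Another phase of the hair cycle, whether by the transgene, by tamoxifen or by chance of age, stays open: cell cycle genes rose with the hair genes (median 1.072), and no group with tamoxifen and without the transgene and no record of the hair cycle is among the samples analysed here.

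Replicate 2 of wounded set A stood apart from the other 3 libraries of its set in hair genes (mean log2(RPKM + 0.5) of 4.80 against 0.528 to 1.17), melanocyte markers (3.29 against 2.01 to 2.1), and Krt31 (5.74), Krt33a (5.83), Krt83 (5.45), Krt85 (5.57), Dct (4.51), Pmel (4.17) and Trpm1 (1.43). RNA of set B mixed into this library is argued against: hair genes lay 33.35% of the way to set B and 256 other genes higher there 13.94%, a difference of -19.41 points beyond the bound of 9.46 set before (-23.31 to -13.47 over 10000 bootstrap resamples). The 325 other genes lower in set B lay at 37.89%, near the hair genes, but with 2 SD of 53.28 points between the other 3 libraries they decide nothing. For RNA of unwounded tamoxifen skin, hair genes lay at 7.12% and 66 other genes at 7.47%, a difference of 0.35 points that passed the bound of 0.31 set before, which by its terms argued against mixing. That bound was too narrow, since it held only the scatter of the other 3 libraries near 0: a spread added after seeing the result gave -0.8 to 2.49 by bootstrap and -0.47 to 1.12 over the source libraries, so such mixing cannot be told apart from a patch of skin with growing hair follicles, a hypothesis that was not tested.

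Other libraries stood apart from the remaining 3 of their group in single values. Replicate 4 of set A held Sox2 at 3.82 RPKM against 1.87 to 2.18. On the log2(RPKM + 0.5) scale it held Sprr2a1 and Sprr2a2 at 6.96 and Sprr2a3 at 9.89. Replicate 1 of set B held BC100530 at 10.8, Krt27 at 8.74, a mean over the SOX2 target sheet of 4.0 and over red blood cell genes of 3.91, and replicate 3 held Trpm1 at 2.13. In unwounded vehicle skin replicate 2 held Erbb2 at 4.08 and a mean over Schwann cell markers of 4.17, replicate 3 Krt25 at 0.954, and replicate 4 Krtap15 at 0.701 and Stfa2l1 at 0.0531. In all, 23 of 255 groups of 4 libraries over 85 values had such a library (9%), where chance gives about 1 in 20. Of these 9 were replicate 2 of set A, and values of related genes are not independent. Unwounded tamoxifen skin, with 3 libraries, was not looked at by this rule. Its replicate 2 correlated across genes at 0.9808 and 0.9792 with replicates 3 and 4, against 0.9936 between those. The library weight of this replicate was 0.295.

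Other splits of the same libraries into groups of the same sizes were counted, the real one included. In unwounded skin only the real split of tamoxifen and vehicle called as many genes (1 of 35, with 9662 genes, highest other 6418). The same held against unwounded vehicle skin for set B (1 of 35, 8244, highest other 0 by limma) and set A (1 of 35, 5541, highest other 45). It also held against unwounded tamoxifen skin for set A (1 of 35, 9107, highest other 7417) and set B (1 of 35, 7633, highest other 3640). With 35 splits this is the smallest share possible, so only a random division of these libraries is argued against. A difference that the libraries of a group share by chance, such as age, would give the same kind of counts. The replicate numbers were taken to pair sets A and B, on these same values. The real split of these sets was therefore compared with those that part all 4 same-numbered pairs. These 8 splits are too few for a share under 0.05: the real one called 4328 genes and the highest other 0 by limma, or 4633 and 2 with the replicate number as a block. The splits that keep same-numbered libraries together called up to 908. For the interaction, of 100 drawn splits that part these pairs 1 called as many by the records (9538, highest other 7198). Under the gene tables' names it was 4 (5565, highest other 7229). These draws exchange treatment names within each wound state. They therefore test for any treatment difference and not for the interaction alone, so they do not exclude chance for the interaction under either naming. Among 100 drawn without regard to pairs it was 1 and 3. The high counts in other splits point to a structure of the samples: the highest other split in unwounded skin put 0 of the 3 tamoxifen libraries into its group of 3 and is nearly the mirror of the real one.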

How the results depend on the processing

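The comparisons under the gene tables' names, their alternatives and the block within the wounded sets were chosen after seeing the data, and the other tests in this part were not. Over all alternatives 16518 values of single genes and lists kept their side of the threshold, 308 lost a call and 98 gained one. No value with a call under the main or the other setting changed direction. Changes of direction among values without a call were not counted. Of values that answer a comparison 413 stayed, 21 were lower and 1 higher past the bounds used. Most of these are counts of genes or lists, which cannot reverse. The correlations of fold changes kept their sign under each alternative within a naming. Between the namings the sign of set A against set B turns, and the Pearson correlation of the wound responses goes from -0.347 by the records to 0.525. With a fold of at least 2 required, counts of genes were 2834 for tamoxifen against vehicle in unwounded skin, 660 for set A against set B, 1862 and 954 for sets B and A against unwounded vehicle, 2778 and 1703 for sets A and B against unwounded tamoxifen, and 4133 and 1475 for the interaction by the records and by the gene tables. This follows from the stricter rule. With a mean RPKM of at least 5, where fewer genes are tested (9010), sets B and A against unwounded vehicle gave 5453 and 3636, and sets A and B against unwounded tamoxifen 6051 and 5084. Library weights raised the count for set A against set B to 7041, with weights from 0.219 (replicate 4 of set A) to 3.564 (replicate 2 of set B), and the cause was not tested. The interaction under the gene tables' names gave 5565 genes. With an estimated correlation between genes 0 lists passed in each of the 8 comparisons, with a lowest adjusted p of 0.388, 0.232, 0.104, 0.26 and 0.36 in the order of the 5 comparisons by the records and 0.0801, 0.0714 and 0.447 under the gene tables' names. Fry called 25, 18, 22, 21, 25, 17, 20 and 16 lists in the same order.

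Leaving out each library in turn gave 8884 to 10013 genes for tamoxifen against vehicle in unwounded skin and 3167 to 5103 for set A against set B. It gave 7471 to 8736 and 4621 to 5872 for sets B and A against unwounded vehicle, 8456 to 9335 and 6723 to 8104 for sets A and B against unwounded tamoxifen, and 9045 to 9870 and 4742 to 5907 for the interaction by the records and by the gene tables. Of 709 single genes and lists, 35 (18 genes and 17 lists) lost a call in at least 1 leave-out. Of those with a call 0 reversed. By the correlations of deviations the replicate numbers were taken to pair sets A and B and no other 2 groups. With the number as a replicate block within the wounded sets the count for set A against set B was 4633 (4194 shared with the 4328), and the block changed no call of the 69 named genes and 16 called lists of this comparison. In that pair of sets 5 of 8 libraries correlated best with their own number. Over the other pairs of groups same-numbered libraries had correlations of -0.304 to 0.425. With a replicate block over all groups the counts in the order above were 9567, 4510, 8387, 9015, 9525, 5651, 7573 and 5519, and with the block within treatment 8058, 8490 and 9137 for the wound comparisons and interaction by the records. Over all comparisons the block over all groups ended 5 calls of named genes and 1 of a list, and added 5 and 1. For set A against unwounded tamoxifen it left 15 called lists, against 16 without it. The block within treatment ended 3 calls of named genes. Quantile normalization put the median of all genes for set B against unwounded tamoxifen at -0.106 (log2), against -0.0508 as deposited. Calls were divided nearly evenly into higher and lower, and the larger side turned in 3 of 8 comparisons with median-of-ratios scaling and in 2 of 8 with quantile normalization, where the share of higher calls moved by at most 2.8 and 8.1 percentage points. With quantile normalization 3852 genes rose and 4436 fell in set B against unwounded vehicle, and 3210 rose and 4980 fell in set B against unwounded tamoxifen skin. Depth may limit low genes such as Pgr, whose means in unwounded tamoxifen skin and in set B lie under the floor of 3 reads for a gene of 1 kb. The floor for the length of Pgr itself was not computed.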

Other observations

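The gene lists in this part, and so its tests, were chosen after the data were seen.

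Interferon-stimulated genes moved together in these samples. All 20 genes of this list were lower in unwounded tamoxifen than in unwounded vehicle skin (median log2 difference -2.61, camera adjusted p = 2.59e-08, and 0.315 with an estimated correlation). The first 3 of the list, Isg15, a ubiquitin-like protein gene, and Ifit1 and Ifit2, which encode antiviral RNA-binding proteins, differed by -2.87 ± 0.30, -2.64 ± 0.33 and -1.98 ± 0.35. All 20 were higher in set A than in set B (1.32, 1.73e-10, and 0.222 with an estimated correlation). Against unwounded vehicle skin 19 were lower in set B (-1.29, 1.33e-05, and 0.255 with an estimated correlation), and in set A 0 passed by limma (0.05, 0.671, and 0.912). Against unwounded tamoxifen skin 20 were higher in set A (2.93, 5.34e-09) and 17 in set B (1.32, 6.15e-06), with 0.281 and 0.478 with an estimated correlation. The interaction was higher for 20 by the records (4.04, 3.61e-09) and for 12 under the gene tables' names (1.04, 4.9e-05), with 0.273 and 0.568 with an estimated correlation.

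Targets of NRF2, a transcription factor of the response to oxidative stress, passed as a list in 1 comparison, set B against unwounded vehicle skin, where 9 of 15 rose and 4 fell (median 0.63, camera adjusted p = 0.0266, and 0.132 with an estimated correlation). In unwounded tamoxifen against vehicle skin 6 rose and 5 fell (0.651), and in set A against set B 2 were higher and 4 lower (0.221). The adjusted p was 0.799 for set A and 0.682 for set B against unwounded tamoxifen, 0.065 for set A against unwounded vehicle, and 0.513 and 0.526 for the interaction by the records and by the gene tables.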
